A study of Zea mays with 18 samples.

How the data were processed

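RNA-seq libraries of maize (Zea mays) inbred W22 roots and shoots were used, 18 in all, in 6 groups of 3 biological replicates. Per the labels' protocols, plants grew in hydroponic solution for 12 days, then with or without iron for 3 days. One set of iron-deprived plants was then given solution with 0.1 mM FeSO4-EDTA, while the other plants received fresh solution of the kind they had, and roots and shoots were collected separately 24 hours later. These groups are called sufficient, deficient and resupplied below. Groups and replicate numbers were taken from the sample titles. The labels call the replicates biological and do not say how many plants each one pooled or whether a root and a shoot library with 1 number came from the same plants.

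The authors deposited 1 table of estimated counts per gene for each library, with 40690 genes in each. The submitters' processing notes name Trim Galore, HISAT2, StringTie and DESeq2, without versions. The genome build and annotation are not given in the sources used here. The estimated counts were whole numbers as deposited, so the rounding applied before the tests changed none of them. Their low values are somewhat more frequent at multiples of 4: 28.9 to 31.1% of low values in root libraries and 28.6 to 31.8% in shoot libraries were such multiples, where 25% would be with no pile-up. Values of 4, 8 and 12 were 1.4 to 1.67 times as frequent as their neighbours in root libraries and 1.38 to 1.89 times in shoot libraries. From this it is inferred, without a further test, that 1 read pair contributed about 4 to many genes, so the totals would overstate the number of fragments. An alternative with counts divided by 4 was added for this reason. Totals ran from 63058129 to 78431980 in roots and from 69390438 to 84318039 in shoots. Whether the spread between 3 replicates or counting noise sets the precision for a given gene was not tested.

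The authors also deposited 6 tables of their own DESeq2 comparisons. Per the file headers, these give a base mean (a normalised signal per gene), a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value. They were used only to set the authors' calls beside those computed from the counts. Their base means differ from the means of the deposited counts, so the 2 kinds of file appear to come from different quantifications.

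Counts were tested with edgeR 4.0.16 in R 4.3.3, using the quasi-likelihood F-test, TMM scaling, the filterByExpr filter and a Benjamini-Hochberg adjusted p under 0.05. The 9 libraries of a tissue shared 1 fit with the group as the only term, and the 3 pairs of conditions were compared in each tissue. Differences between tissues were tested as interaction contrasts, the root effect minus the shoot effect, in a fit over all 18 libraries. "Rose", "fell" and "called" below refer to this test. Standard errors of log2 fold changes were derived from the F statistic. Printed CPM values were computed with edgeR after TMM scaling over all 18 libraries and are given as mean ± SD of 3 libraries. Principal components were computed per tissue from log2 CPM.

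The design, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The 27 gene lists fixed then, including iron uptake, phytosiderophore and strigolactone genes, could not be used. The files do not pair their identifiers with gene names, and 0 of the identifiers occur among the 49888 genes of the B73 (NAM-5.0) name table that was at hand. The rule fixed for that case names, per comparison, the 2 rising and 2 falling identifiers with the largest log2 fold change among calls with at least 10 CPM in the higher group. No function is given for any of them. Groups of genes are instead described by abundance and by tissue. The 100 genes with the highest mean CPM in a tissue are called the most abundant, and genes with at least 8 times the mean CPM of the other tissue, after adding 0.1 CPM, are called root-preferring or shoot-preferring. These groups were chosen after the data were examined. Their shares among calls were compared with those among tested genes by Fisher's exact test, two-sided, adjusted over 60 tests. Genes are not independent replicates, so these p-values describe lists of genes. The tests did not match genes for abundance. Abundant genes are called more easily, so part of the shares may follow from abundance.

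The same steps were tested on simulated counts in which 200 genes changed, with a single simulated data set per comparison. The changed genes had a mean of at least 1 CPM in the tissue, and in both tissues for the tissue difference. The recovery rates therefore do not cover genes under 1 CPM. In the simulated root comparison of deficient with sufficient plants, over 26577 genes, 60% of changes of 2-fold and 95% of changes of 4-fold were recovered, and 5.5% of calls were false. In the simulated shoot comparison, over 26318 genes, these values were 82%, 96% and 10.6%. The share of false calls in that data set was above the nominal level. In the simulated tissue difference, over 27914 genes, they were 53%, 91% and 4%. Overlaps between comparisons that share libraries were set beside 20 simulations per tissue in which no gene changed.

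Libraries were compared before averaging. Over the 18 pairs of replicates, the chi-square per degree of freedom ran from 6.54 to 16.3. It was computed on counts divided by 4. If about 4 counts stand for a read pair, counting noise alone would put it near 1. The values lie above that, and no replicate is a copy of another. RNA of the other tissue was looked for with 95 genes abundant in shoots and 30 abundant in roots that were near 0 in the other tissue. Their level, as a share of that in the tissue of origin, was 0.0313 to 0.26% in root libraries and 0.00476 to 0.186% in shoot libraries. The genes were chosen for at least 100 CPM in their tissue and a median of at most 0.5 CPM in the other. A low typical share follows from that choice, so only a library that stands apart could be seen. The alternatives tried were RLE size factors, total counts without a composition factor, other filters, DESeq2 1.42.0, a minimum log2 fold change of 1, a replicate block, fits to the 6 libraries compared and leaving out each replicate. A robust fit, counts divided by 4, DESeq2 with a beta prior (which shrinks log2 fold changes towards 0) on the 6 libraries compared, and a fit without genes at 0 in 1 library and at 100 or more in another of the same group were added after seeing the data.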

Results

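Gene expression was measured by RNA-seq in roots and shoots of maize inbred W22 under iron sufficiency, iron deficiency and iron resupply, with 3 biological replicates of each. Root libraries held 63058129 to 78431980 estimated counts and between 27124 and 27550 genes with a count. Shoot libraries held 69390438 to 84318039 estimated counts and between 26946 and 27540 genes. The first 2 principal components held 20.4% and 17.5% of the variance among root libraries and 17.7% and 16% among shoot libraries, and the 3 conditions lay apart on them in both tissues. The comparisons ask which genes respond to iron deprivation, how far 1 day of renewed iron takes them back, and where roots and shoots differ.

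**Figure D1:**
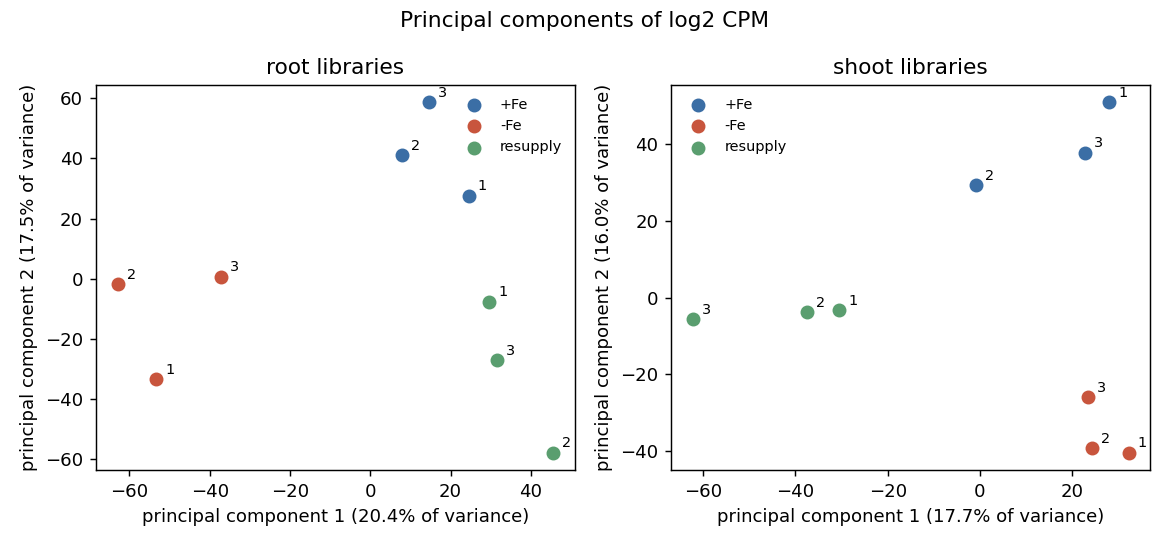
Principal components 1 and 2 of log2 CPM for root libraries (left) and shoot libraries (right), with each point a library, its replicate number beside it and its color giving the condition. Deficient roots lie between -62.92 and -37.27 on component 1 while the other root libraries lie above 0, and resupplied shoots lie between -62.29 and -30.54.

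**Figure D2:**
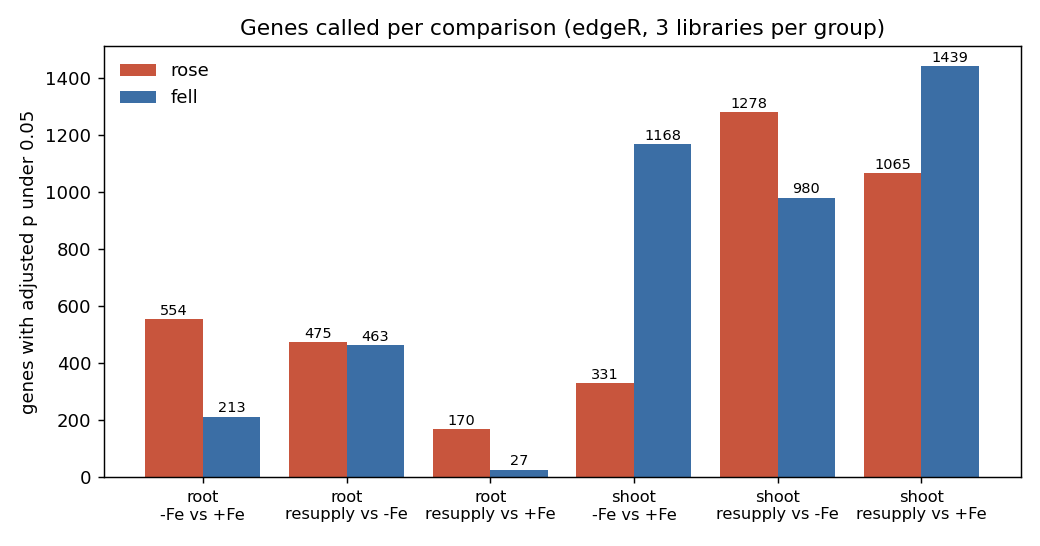
Number of genes that rose (red) or fell (blue) at an adjusted p under 0.05 in each comparison of 2 conditions within a tissue, as bars from 0 with the counts above them. Shoots had more calls than roots in each of the 3 comparisons, from 1499 against 767 for deficiency to 2504 against 197 for resupplied against sufficient plants. Among changes of at least 2-fold this order does not hold for deficiency, with 157 in shoots against 307 in roots. It does not hold for resupplied against deficient plants either, with 291 against 293. In simulated deficiency data, changes of 2-fold were recovered more often in shoots, 82% against 60%, so the counts may also reflect precision.

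In roots, most of the genes called under iron deficiency rose. Of 26577 genes tested, 554 rose and 213 fell in deficient against sufficient roots, and 248 of the risers and 59 of the fallers changed by at least 2-fold. Genes expressed mainly in roots made up much of the response: 212 of the 554 risers, or 38.3%, were root-preferring, against 6.63% of the genes tested (adjusted p = 1.9e-105, Fisher's exact test). They were also 45 of the 213 fallers, or 21.1% (adjusted p = 7.3e-12). When the preference was taken from sufficient plants alone, 153 of the risers, or 27.6%, were root-preferring (adjusted p = 2.3e-55). Of the fallers it was then 50, or 23.5% (adjusted p = 2.3e-15, Fisher's exact test), so the preference is not particular to the risers. Abundance was not matched in these tests: the risers had a median of 29.7 CPM in roots against 12.4 for the genes tested. Among the 100 most abundant root genes, 21 rose and 4 fell, and this group's share of all counts was 13.8 ± 0.36% in deficient roots against 12.3 ± 0.41% in sufficient ones (SD, n = 3).

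The riser with the largest change by the naming rule was Zm00004b018725, which went from 0.246 ± 0.141 to 20.3 ± 2 CPM (SD, n = 3), a log2 fold change of 6.32 ± 0.44 (SE, adjusted p = 2e-05). Zm00004b035170 rose from 0.196 ± 0.24 to 14.1 ± 2.07 CPM, with a log2 fold change of 6.15 ± 0.74 (adjusted p = 0.00088). In the authors' deposited table its log2 fold change is 0.29 with an adjusted p of 0.18, and DESeq2 with a beta prior gave 0.30 ± 0.14 (adjusted p = 0.23) from the deposited counts. Zm00004b035906 fell from 21.8 ± 3.01 to 2.01 ± 1.8 CPM (log2 fold change -3.48 ± 0.51, adjusted p = 0.0032). Zm00004b022755 fell from 12 ± 1.49 to 1.24 ± 0.0666 CPM (log2 fold change -3.30 ± 0.19, adjusted p = 6.6e-06). The number of calls depended on single libraries: it was 423 and 436 without deficient library 1 or 2, and 433 and 502 without sufficient library 1 or 3. That last library also held the most signal of shoot-abundant genes, 0.26% of their level in shoots. Without deficient library 3 the excess of risers was nearly gone, with 527 genes up and 495 down. DESeq2 called 1599 genes, with 38.1% of them lower against 27.8% in edgeR, and total-count scaling gave 37.8% lower.

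Against deficient roots, 475 genes rose and 463 fell in resupplied roots. This balance depends on single libraries: 158 rose and 256 fell without deficient library 1, 145 and 231 without library 2, and 901 and 514 without library 3. Without resupplied library 1, 2 or 3, 270, 198 and 283 rose and 339, 259 and 320 fell. Root-preferring genes were 145 of those that fell, or 31.3% (adjusted p = 2.1e-58, Fisher's exact test), and 77 of those that rose, or 16.2% (adjusted p = 6.9e-13). With the preference taken from sufficient plants these were 123, or 26.6% (adjusted p = 1.6e-42), and 70, or 14.7% (adjusted p = 1.7e-10). Zm00004b018725, which deficiency had raised, fell to 0.345 ± 0.202 CPM, a log2 fold change of -5.83 ± 0.42 (SE, n = 3, adjusted p = 5.3e-05). Zm00004b019773 fell from 16.1 ± 3.43 to 0.36 ± 0.337 CPM (log2 fold change -5.47 ± 0.64, adjusted p = 0.00098). Zm00004b008971 rose from 1.43 ± 1.38 to 30.7 ± 8 CPM (log2 fold change 4.47 ± 0.71, adjusted p = 0.0065), and its call was lost in a robust fit (adjusted p = 0.05), in DESeq2 with a beta prior (0.12) and in the authors' deposited table (0.1). Zm00004b037582 rose from 0.988 ± 0.628 to 20.6 ± 7.45 CPM (log2 fold change 4.42 ± 0.54, adjusted p = 0.0014).

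Of the 767 root genes called in deficiency, 403, or 52.5%, were called in the opposite direction on resupply (38.1 to 65.8% without 1 library). Between resupplied and sufficient roots, 695 of the 767, or 90.6%, were not called. Of all genes tested only 0.741% were called there, so a high share not called is no measure of return. The deficiency genes were called there more often than genes at large, which the shared sufficient libraries may favour. Genes that deficiency had lowered had a median log2 difference from sufficient roots of -0.75 in deficient and -0.09 in resupplied plants, and for 131 of these 213 the reversal was called. Genes that deficiency had raised went from a median of 0.94 to 0.31, with 272 of 554 reversals called. The genes were chosen by their deficiency call, which favours large first values, so part of each drop may follow from that choice. After resupply, 87.4% of the raised genes were still above sufficient roots and 61% of the lowered ones still below. Zm00004b022755 was at 12.4 ± 2.57 CPM after resupply (SD, n = 3), 0.05 ± 0.17 (SE) log2 units from sufficient roots. Both comparisons use the same 3 deficient libraries, which makes opposite changes likelier by chance. Independent lists of these sizes would share 9.65 risers and 3.81 fallers. Simulated data with no true change gave a mean overlap of 0 genes, but with only 0.4 and 0.2 calls on average they say little about lists of this size. The correlation of log2 changes across genes was -0.55, against -0.5 in simulation, and the covariance was -0.236 against -0.0859. With the deficient libraries divided 1 and 2 between the comparisons in all 6 ways, a check added after seeing the data, 114 to 179 genes were called in opposite directions against 1.82 to 5.81 for independent lists, and the covariance was -0.168 to -0.108. The lone library is taken there to vary like the other groups. Part of the 403 may still come from the shared libraries. The count of genes called on resupply was 414, 376 and 1415 without deficient library 1, 2 or 3, and 609, 457 and 603 without resupplied library 1, 2 or 3. DESeq2 called 2205.

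After 1 day of resupply, roots still differed from sufficient roots at 197 genes, of which 170 were higher and 27 lower. Root-preferring genes were 65 of the 170, or 38.2% (adjusted p = 2.7e-32, Fisher's exact test), and 33, or 19.4% (adjusted p = 2e-08), with the preference taken from sufficient plants. Of the 170, 70 had also risen in deficiency, where independent lists would share 3.54. Unchanged simulated groups, with hardly any calls, shared 0.05 on average. In deficiency 99 of the 170 had not been called, but their median log2 change there was already 0.33, which the shared sufficient libraries may favour. Of the 99, 53 were also called higher than in deficient roots, so the 99 are not all new to resupply. With the sufficient libraries divided 1 and 2 between the comparisons, 0 to 20 genes were called in the same direction against 0.0378 to 0.64, from only 3 to 117 calls for resupply, so part of the 70 may come from sharing them. The largest rises were in Zm00004b016768, from 1.64 ± 1.55 CPM in sufficient to 77 ± 30.3 in resupplied roots (SD, n = 3), and Zm00004b006197, from 1.17 ± 0.161 to 24.1 ± 9.7. Their log2 fold changes were 5.55 ± 0.74 (SE, adjusted p = 0.0078) and 4.37 ± 0.4 (adjusted p = 0.0016). Both were already higher in deficient roots, at 23.7 ± 14.3 and 9.46 ± 4.24 CPM, with adjusted p of 0.014 and 0.0014 against sufficient roots. A robust fit gave Zm00004b016768 an adjusted p of 0.083. Zm00004b034501 fell from 18.4 ± 4.9 to 6.87 ± 1.4 CPM (log2 fold change -1.41 ± 0.23, adjusted p = 0.018) and Zm00004b014754 from 11.1 ± 2.7 to 4.59 ± 0.277 CPM (-1.27 ± 0.24, adjusted p = 0.041).

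Those last 2 calls were lost with fewer libraries while the change stayed negative. Leaving out any of the 6 libraries compared ended the call of Zm00004b014754, with log2 fold changes of -1.05 to -1.37 and adjusted p of 0.065 to 0.16. Leaving out sufficient library 1 or 3 or resupplied library 1 or 2 ended that of Zm00004b034501, with log2 fold changes of -1.19 to -1.47 and adjusted p of 0.054 to 0.093. The total of 197 calls fell to 61, 75 and 121 without sufficient root library 1, 2 or 3 and to 69 and 117 without resupplied library 2 or 3, and DESeq2 gave 631, of which 31.9% were lower against 13.7% in edgeR.

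In shoots, deficiency lowered more genes than it raised. Of 26318 genes tested, 1168 fell and 331 rose in deficient against sufficient shoots, with median log2 changes of -0.52 and 0.52, and 157 of the 1499 changed by at least 2-fold. The fall was concentrated in abundant and shoot-preferring genes. Of the 100 most abundant shoot genes, 67 fell and 2 rose (adjusted p = 2e-65 for the falls, Fisher's exact test), and with total-count scaling these numbers were 62 and 7. This group held 23.4 ± 0.68% of all counts in sufficient shoots and 17.3 ± 0.33% in deficient shoots (SD, n = 3), ranges of 22.8 to 24.1% and 16.9 to 17.6% that do not overlap. Shoot-preferring genes were 557 of the 1168 fallers, or 47.7%, against 7.96% of the genes tested (adjusted p = 1e-300, the smallest value written). They were more frequent among the risers too, though less so, at 47 of 331, or 14.2% (adjusted p = 0.00019). With total-count scaling, 362 shoot-preferring genes fell and 175 rose. Abundance was not matched here either: the fallers had a median of 60.3 CPM in shoots against 14.1 for the genes tested.

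Zm00004b019793 fell from 3040 ± 214 to 722 ± 137 CPM (SD, n = 3), with a log2 fold change of -2.07 ± 0.13 (SE, adjusted p = 3.5e-06). Zm00004b019791 fell from 2030 ± 197 to 421 ± 84.9 CPM, with a log2 fold change of -2.27 ± 0.13 (adjusted p = 3.5e-06). Zm00004b017752 rose from 4.63 ± 0.118 to 31.2 ± 2.33 CPM, with a log2 fold change of 2.75 ± 0.11 (adjusted p = 1.4e-07). It rose in roots as well, from 26.3 ± 3.33 to 214 ± 11.3 CPM (log2 fold change 3.00 ± 0.17, adjusted p = 4.6e-06). Zm00004b038610 rose from 3.7 ± 2.28 to 17.6 ± 4.98 CPM (log2 fold change 2.25 ± 0.36, adjusted p = 0.0033). The balance of directions depends on the scaling. Total counts alone shift the median log2 change of all genes by 0.175 and call 3173 risers and 630 fallers, 16.6% lower against 77.9%, so all directions here are relative to the TMM scale, on which the median was 0.009. Calls numbered 846, 1675 and 920 without sufficient shoot library 1, 2 or 3, and 882, 883 and 807 without deficient library 1, 2 or 3. The 1675 were 563 risers and 1112 fallers. DESeq2 called 2451.

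Against deficient shoots, 1278 genes rose and 980 fell in resupplied shoots, and 291 of the 2258 changed by at least 2-fold. This total is above the 1499 of deficiency with TMM, but with total-count scaling the order reverses, at 2457 against 3803. Of the 100 most abundant genes, 44 rose and 7 fell (adjusted p = 1e-30 for the rises, Fisher's exact test), or 35 and 10 with total-count scaling, and the group's share of counts was 19.1 ± 0.59% (SD, n = 3). Shoot-preferring genes were 374 of the risers, or 29.3% (adjusted p = 1.8e-118), and 210 of the fallers, or 21.4% (adjusted p = 6e-41), but with total-count scaling 309 rose and 296 fell. Zm00004b019791 and Zm00004b019793 rose to 1360 ± 92.2 and 2040 ± 161 CPM, and stayed below sufficient shoots by -0.57 ± 0.13 and -0.57 ± 0.12 log2 units (SE, adjusted p = 0.015 and 0.012). Zm00004b038609 fell from 18.5 ± 4.21 to 1.64 ± 0.447 CPM (log2 fold change -3.50 ± 0.37, adjusted p = 0.00019), and Zm00004b038610, with the next identifier in the list, to 1.62 ± 0.394 CPM (-3.44 ± 0.39, adjusted p = 0.00028).

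Zm00004b031844 rose from 3.65 ± 0.546 to 30.3 ± 13.3 CPM on resupply (SD, n = 3; log2 fold change 3.05 ± 0.75, SE, adjusted p = 0.025). Zm00004b038322 rose from 5.22 ± 0.682 to 36.1 ± 7.61 CPM (log2 fold change 2.79 ± 0.49, adjusted p = 0.0043). The call for Zm00004b031844 was lost without deficient shoot library 1, 2 or 3 (adjusted p = 0.093, 0.073 and 0.091) and without resupplied library 1 or 2 (0.06 and 0.089), at log2 fold changes of 2.72 to 3.18, and both calls were lost in a robust fit (0.16 and 0.056). The total was 1272 and 1418 without deficient shoot library 1 or 3 and 1408 and 1460 without resupplied library 2 or 3. With total-count scaling, 63.9% of calls were lower against 43.4%.

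Of the 1499 shoot genes called in deficiency, 47.4% were called in the opposite direction on resupply (38.7 to 61.1% without 1 library). Between resupplied and sufficient shoots, 959 of the 1499, or 64%, were not called. Of all genes tested 9.51% were called there, so the deficiency genes were called more often than genes at large. The shared sufficient libraries may favour this. Genes that deficiency had lowered went from a median log2 difference of -0.52 to -0.21, with 585 of 1168 reversals called. Those it had raised went from 0.52 to 0.29, with 126 of 331 called. As in roots, part of these drops may follow from choosing genes by their deficiency call. After resupply, 78.4% of the lowered genes were still below sufficient shoots and 72.8% of the raised ones still above. Zm00004b017752 kept a log2 difference of 1.58 ± 0.1 (SE, n = 3, adjusted p = 2.9e-05) in resupplied shoots and 1.61 ± 0.16 (adjusted p = 0.0016) in resupplied roots. Independent lists would share 12.3 risers and 56.7 fallers, and simulated data without change, with 0.95 and 0.55 calls on average, a mean of 0.15 genes. The correlation across genes was -0.49, as in simulation, and the covariance was -0.157 against -0.0735. With the deficient libraries divided in the same way, 119 to 240 genes were called in opposite directions against 3.92 to 12 for independent lists, with a covariance of -0.0816 to -0.0501. Part of the larger overlap may come from the shared libraries.

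**Figure D3:**
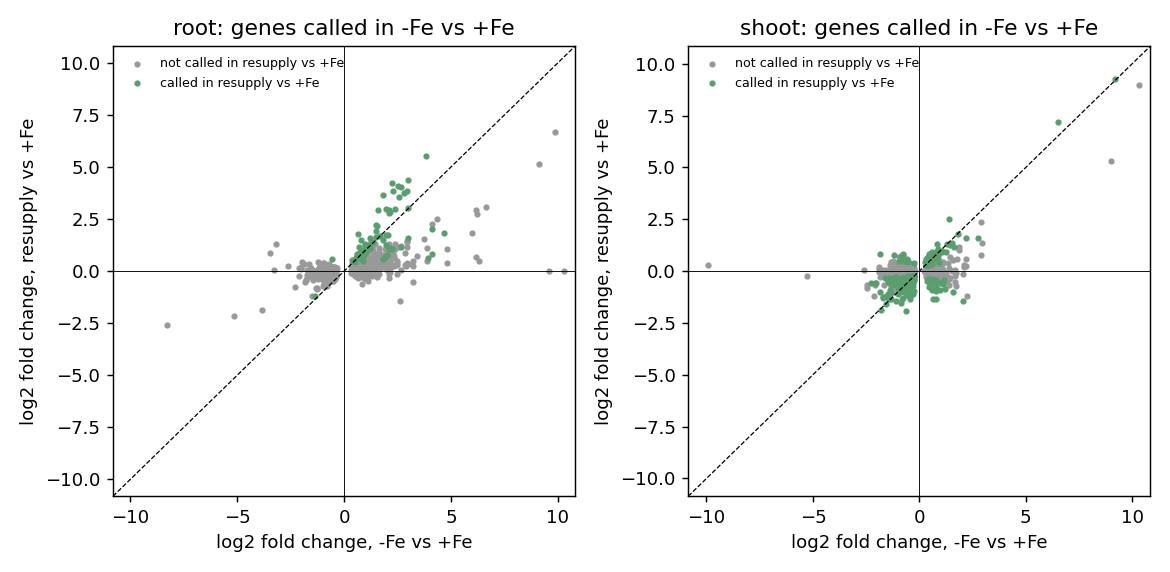
Log2 fold change of resupplied against sufficient plants (y axis) plotted on that of deficient against sufficient plants (x axis) for the 767 root genes and 1499 shoot genes called in deficiency, with each point a gene, green where the y value was called and the dashed line marking equal change. Median values fall from 0.94 to 0.31 for genes that rose in roots and from 0.52 to 0.29 for genes that rose in shoots. Part of these falls may follow from choosing the genes by their call on the x axis. Points far out include genes with libraries at 0, whose fitted values are not exact.

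Resupplied shoots differed from sufficient shoots at 2504 genes, with 1065 higher and 1439 lower. Of the 100 most abundant genes, 65 were lower and 1 higher (adjusted p = 2.3e-56 for the lower ones, Fisher's exact test), or 55 and 4 with total-count scaling. Shoot-preferring genes were 481 of the 1439, or 33.4% (adjusted p = 3.8e-183), and with total-count scaling 358 were lower and 112 higher. Of the 1439, 373 had fallen in deficiency too, against 63.9 for independent lists, and 1039 had not been called in deficiency. The 1039 had a median log2 change of -0.15 there, and 497 of them were also called lower than in deficient shoots. Of the 1065, 127 had risen in deficiency, against 13.4, and 925 had not been called. The 925 had a median log2 change of 0.19 in deficiency, and 290 of them were also called higher than in deficient shoots. Unchanged simulated groups, again with hardly any calls, shared 0.3 genes on average. With the sufficient libraries divided 1 and 2 between the comparisons, 58 to 218 genes were called in the same direction against 7.97 to 29 for independent lists, and part of the larger overlap may come from sharing them. Zm00004b012790 fell from 19.3 ± 0.486 to 5.1 ± 0.608 CPM (SD, n = 3; log2 fold change -1.92 ± 0.15, SE, adjusted p = 1e-04), and it was also lower in resupplied than in sufficient roots (-1.25 ± 0.23, adjusted p = 0.033). Zm00004b006391 rose from 8.8 ± 3.88 to 34.1 ± 9.82 CPM (1.96 ± 0.33, adjusted p = 0.0041).

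Zm00004b024803 fell from 17.6 ± 0.694 CPM in sufficient to 3.64 ± 1.65 in resupplied shoots (SD, n = 3; log2 fold change -2.26 ± 0.54, SE, adjusted p = 0.022), while the authors' deposited table gives 0.03 with an adjusted p of 0.88. Zm00004b038322 rose from 9.79 ± 8.8 to 36.1 ± 7.61 CPM (1.88 ± 0.47, adjusted p = 0.028), against an adjusted p of 0.089 in the authors' deposited table. The call for Zm00004b024803 was lost without sufficient shoot library 1 or 3 (adjusted p = 0.056 and 0.058) and resupplied library 1 or 3 (0.074 and 0.087), and in a robust fit (0.12). That for Zm00004b038322 was lost without sufficient library 3 (0.11) and resupplied library 1, 2 or 3 (0.059, 0.086 and 0.062), in the fit to the 6 libraries compared (0.054), in a robust fit (0.14) and in DESeq2 with a beta prior (0.11). The total of 2504 was 1334, 3032 and 1456 without sufficient library 1, 2 or 3 and 1471 and 1102 without resupplied library 2 or 3. Total-count scaling shifts the median by 0.101 and gives 28.2% lower calls against 57.5%.

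**Figure D4:**
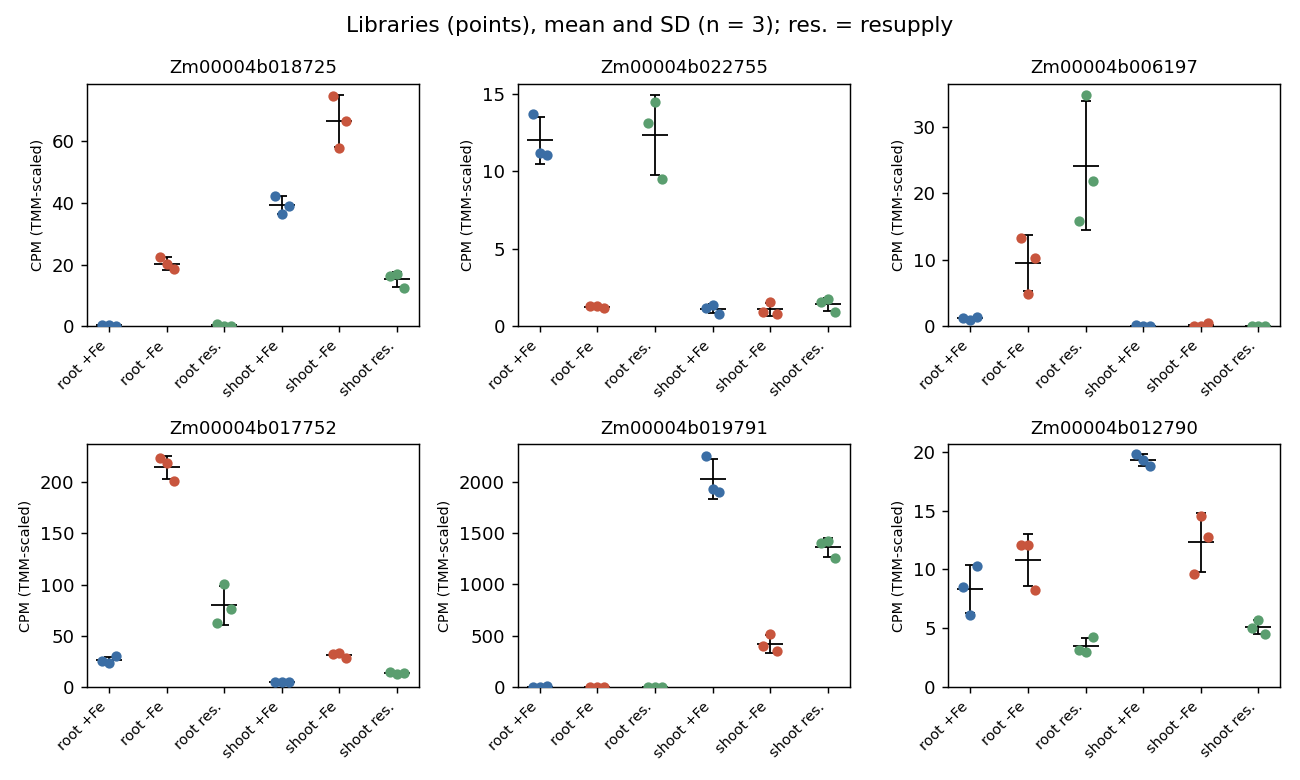
CPM after TMM scaling of 6 identifiers in each library (points; blue sufficient, red deficient, green resupplied) with the group mean and SD (n = 3) in black, on linear axes from 0 that differ between panels. Zm00004b018725 reached 20.3 CPM in deficient roots from 0.246, and Zm00004b019791 went from 2030 to 421 and back to 1360 CPM in shoots.

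Roots and shoots shared part of their response. Among 25142 genes tested in both tissues, 29 rose in deficiency in both, where 6.04 would be shared by chance (adjusted p = 1.5e-11, Fisher's exact test), and 30 fell in both against 9 (adjusted p = 1.7e-08). On resupply against deficiency, 120 rose in both against 22.4 (adjusted p = 5.4e-53) and 83 fell in both against 15.6 (adjusted p = 8.4e-36). Between resupplied and sufficient plants, 27 genes were higher in roots and lower in shoots against 8.55 by chance (adjusted p = 2e-07), 12 were lower in both against 1.48 (adjusted p = 1.7e-08), and 5 were higher in both against 6.51 (adjusted p = 0.75). Zm00004b017752 rose in deficiency in both tissues and its tissue difference was 0.28 ± 0.19 (SE, n = 3, adjusted p = 0.51).

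The interaction test found 608 genes whose response to deficiency differed between tissues, with 414 effects more positive in roots and 194 more positive in shoots. Of these, 210 were called in roots alone, 211 in shoots alone, 23 in both and 164 in neither. For resupply against deficiency, 405 genes differed, 184 more positive in roots and 221 in shoots. Zm00004b018725 rose in deficiency in both tissues and more so in roots, where it started from 0.246 CPM against 39.3 ± 2.96 CPM in shoots (SD, n = 3). Zm00004b019773 rose in deficient roots and stayed between 0.216 and 0.306 CPM in the shoot groups. Total-count scaling shifts the median tissue difference by -0.237 for deficiency and 0.103 for resupply. With it 2665 genes were called for deficiency, 89% of them more positive in shoots against 31.9%, and for resupply the share was 33.5% against 54.6%. Leaving out 1 library gave from 280 (deficient root library 1) to 1129 genes (deficient root library 3) for deficiency and from 236 (deficient root library 2) to 576 (deficient root library 3) for resupply, and DESeq2 gave 1652 and 1127.

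The authors' deposited tables call more genes than edgeR did in each comparison at an adjusted p under 0.05. They list 1722, 2510 and 701 genes for root deficiency, root resupply against deficiency and root resupply against sufficiency, and 2558, 3952 and 3738 for the same comparisons in shoots. Between 95.6% and 97.8% of the edgeR calls were called there as well, all with the same sign. In the authors' deposited tables Zm00004b018725 has a log2 fold change of 4.24 in deficient roots, Zm00004b017752 one of 2.51 in deficient shoots and Zm00004b019791 one of -2.15. For 507 of the 8162 edgeR calls also listed there, the authors' log2 fold change is smaller in size by over 0.5. Some of these lie far nearer to 0, such as 0.42 against 5.55 for Zm00004b016768 in resupplied against sufficient roots. In resupplied against deficient roots they include -0.7 against -5.47 for Zm00004b019773 and 0.59 against 4.42 for Zm00004b037582. Others are -0.87 against -3.48 for Zm00004b035906 in deficient roots and 0.74 against 2.25 for Zm00004b038610 in deficient shoots. On the deposited counts, DESeq2 with a beta prior gave 0.48, -0.91, 1.12, -0.90 and 0.74 for these identifiers, in the same order.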

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

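Of the tests below, the comparison of base means with the deposited counts, the alternatives with counts divided by 4 and with a beta prior and the number of splits drawn for the tissue differences were chosen after results had been seen, the latter lowered to limit run time after a larger draw had been seen. Single libraries that stand apart were not tested for, because the rule set for this applies to groups of 4 to 10 libraries.

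The response to deficiency differed between tissues for 608 genes and that to resupply against deficiency for 405, by the interaction test of edgeR. Of 25 drawn splits of the libraries within tissues, the real one included, 1 gave as many genes for deficiency, the real one, and the highest other gave 312. For resupply it was again 1 of 25, with a highest other of 189. A share of 1 in 25 is under 0.05 but is the smallest that 25 splits can give. Such splits ask whether the conditions differ at all, not whether both tissues respond alike. They therefore cannot decide whether the tissues differ. Single libraries moved both counts: for deficiency 298 and 381 genes were called without sufficient root library 1 or 2, 280, 371 and 1129 without deficient root library 1, 2 or 3, 329 and 326 without sufficient shoot library 1 or 3, and 345, 329 and 355 without deficient shoot library 1, 2 or 3. For resupply 236 were called without deficient root library 2, 257, 270 and 245 without deficient shoot library 1, 2 or 3, and 270 and 241 without resupplied shoot library 1 or 2.

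Several identifiers named in the results differed between tissues, given here as the root log2 effect minus the shoot one. For deficiency the difference was 5.58 for Zm00004b018725, 4.03 for Zm00004b016768, 6.09 for Zm00004b019773, -3.21 for Zm00004b022755 and -3.68 for Zm00004b035906. For resupply against deficiency it was -3.73 for Zm00004b018725, -5.89 for Zm00004b019773, 2.93 for Zm00004b022755, 2.97 for Zm00004b037582 and -1.37 for Zm00004b014754. The adjusted p of the deficiency difference of Zm00004b019773 was 0.013, and 0.052 without sufficient shoot library 2.

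The identifiers named for their tissue differences, the largest among calls with at least 10 CPM in the higher group, mostly have a tissue with hardly any counts. Zm00004b023744 (-7.93 for deficiency), Zm00004b039982 (-8.12 for deficiency) and Zm00004b015345 (-6.76 for deficiency, 6.06 for resupply) had 0 counts in all 3 deficient root libraries and at most 49 in another root library, while their shoot groups had 29.5 CPM or more. Zm00004b003713 (6.09 for deficiency) had 0 in all sufficient root libraries and at most 12 in the other root libraries. Zm00004b000557 (9.62 for resupply) had 0 in all resupplied shoots and at most 62 in the other shoots, Zm00004b016439 (-7.68) 0 in all deficient shoots and at most 25 elsewhere in shoots, and Zm00004b039558 (-7.03) 0 in all sufficient and deficient shoots and at most 9 in resupplied ones. A value fitted against a group at 0 depends on the prior count and bounds nothing, so these numbers rank genes and measure no fold. With counts divided by 4, the calls of Zm00004b003713, Zm00004b000557, Zm00004b015345, Zm00004b016439 and Zm00004b039558 were lost (adjusted p = 0.082, 0.08, 0.11, 0.064 and 0.12). Of 21 alternatives, that one included, the call was lost in 12 for Zm00004b003713, 11 for Zm00004b015345, 7 each for Zm00004b000557 and Zm00004b039982, 4 for Zm00004b016439, 1 for Zm00004b039558 and 0 for Zm00004b023744. The other losses came from leaving out 1 library or from the replicate block. Without 1 library, the adjusted p reached 0.11 for Zm00004b003713 (sufficient root library 1), 0.094 for Zm00004b015345 (deficient root library 2), 0.074 for Zm00004b000557 (deficient shoot library 3), 0.072 for Zm00004b039982 (deficient root library 1) and 0.056 for Zm00004b016439 (deficient shoot library 3). Of the 608 genes, 61 had under 1 CPM in a tissue, but among the 86 with a log2 difference of at least 2 it was 55.

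The excess of falling genes in deficient shoots was weighed against 2 technical explanations and against the iron treatment that the design names. The split depends on the scaling between libraries, which stays open: with total counts alone, which shift the median gene by 0.175, 16.6% of calls fell, against 77.9% with TMM and 77.1% with RLE factors, and no spike-in or other absolute measure that would tell which scale is right is used here. Greater power for abundant genes is not settled, since 54.5% of calls fell among the least abundant of 3 equal classes of genes, 64.5% in the middle class and 85.3% in the most abundant. What the scalings share is that abundant genes fell relative to the rest, with 62 of the 100 most abundant lower even by total counts. A lower output of the most abundant shoot transcripts under iron deficiency remains a candidate explanation, as a hypothesis that relative counts cannot separate from a rise of all other genes.

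The larger number of calls and, at some genes, smaller fold changes in the authors' tables were weighed against 3 explanations, with no biological one tested. The choice of test could account for most of the calls when no prior is used. DESeq2 without a prior was fitted to the deposited counts of the 9 libraries of a tissue. The authors' count divided by that of this fit was 1.09 in the median of 6 comparisons, near the limit of 1.1 set beforehand. It ran from 1.02 to 1.27 over them. DESeq2 with a beta prior on the 6 libraries compared called fewer genes than the authors in each comparison. For deficiency, resupply against deficiency and resupply against sufficiency it called 1460, 2126 and 629 in roots against 1722, 2510 and 701. In shoots it called 2135, 3321 and 3016 against 2558, 3952 and 3738. Shrinkage could account for most of the smaller changes. Of 8162 edgeR calls also listed by the authors, 507 had an authors' log2 fold change smaller in size by over 0.5. Of the 507, 79.7% lie within 0.2 of DESeq2 with a beta prior on the deposited counts. Over all edgeR calls the median distance from the authors' values was 0.01 with the prior and 0.05 without. Zm00004b024803 is not covered: for resupplied against sufficient shoots the prior gave -1.62, against 0.03 from the authors. Another quantification could add differences at some genes: in the median comparison 27% of genes with a base mean of 100 or more differed by over 10% from the deposited counts. Zm00004b030197, chosen after its values were seen, has a log2 fold change of 4.76 and an adjusted p of 1.1e-134 for resupplied against deficient shoots in the authors' deposited table, while the deposited counts are 0 in all 3 deficient shoots and 581, 0 and 0 in resupplied ones.

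Some genes are at 0 in 1 library and at 100 or more in another of the same group: 156 genes with 343 such zeros. Estimates moved to genes with adjacent identifiers do not account for most of them, since the median gain of those neighbours was 0 of the lost CPM, but 18.4% of the zeros came with a gain of at least 0.5 of it and stay open. A few failed libraries are argued against as well, since the library with the most zeros, resupplied root library 2, held 9.91% of them. Exchange of reads with similar genes elsewhere in the genome was not tested, and no biological explanation was tested. Between 0 and 11 such genes were among the calls of any comparison within a tissue.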

How the results depend on the processing

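The robust fit, the counts divided by 4, the fit without genes at 0 in 1 library, DESeq2 with a beta prior and the reversed shares without 1 library were chosen after seeing the data. Of 576 alternative values of the 32 named results, 500 kept their direction and their call, 76 kept the direction and lost the call, and 0 reversed; 16 of the 32 lost the call under at least 1 alternative. For counts of calls, the order is root deficiency, root resupply against deficiency, root resupply against sufficiency, the same in shoots, then the tissue differences for deficiency and for resupply. A minimum log2 fold change of 1 left 307, 293, 106, 157, 291, 196, 256 and 239 genes, by construction a subset of the calls. DESeq2 raised the counts to 1599, 2205 and 631 in roots, to 2451 for shoot deficiency and to 1652 and 1127 for the tissue differences, and moved the share of deficiency calls reversed on resupply from 52.5% to 56.1% in roots and from 47.4% to 41.5% in shoots; the cause was not tested. With a beta prior and the 6 libraries compared, DESeq2 gave 1460, 2126 and 629 in roots. Total counts gave 3803 for shoot deficiency and 2665 for its tissue difference, with the shift of all genes given above. Leaving out 1 library, which also removes samples, gave 423 to 1022, 376 to 1415, 61 to 195, 807 to 1675, 1272 to 1586, 1102 to 3032, 280 to 1129 and 236 to 576 genes, and reversed shares of 38.1 to 65.8% in roots and 38.7 to 61.1% in shoots over the 9 libraries of a tissue. These shares rose without sufficient root library 1, 2 or 3 and fell without any 1 resupplied library in both tissues. Removal of deficient root library 3 raised 4 of these counts to their highest values of 1022, 1415, 1129 and 576. It also raised the reversed share in roots to 65.6%. Removal of sufficient shoot library 2 gave the highest values of 1675 and 3032 in shoots. The cause was not tested for either library. The reversed share in shoots was 61.1, 39.2 and 57.5% without sufficient shoot library 1, 2 or 3, and 56.7 and 50.9% without deficient shoot library 2 or 3. RLE factors, the other filters, the fits to 6 libraries and the other 3 added alternatives kept each count within 1.5 times its value.

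Little sign was seen that the replicate numbers pair the libraries, and pairing is not excluded. Deviations of libraries with the same number correlated between -0.11 and 0.159 within tissues, with 3 of 18 pairs over 0.1, and 5 of 18 libraries correlated best with their own number. Between tissues, libraries with the same number correlated between -0.111 and 0.12, with 2 of 27 pairs over 0.1. With the replicate number as a block, the counts were 529, 628, 131, 1571, 2369, 2564, 455 and 409. For the last 2, the tissue differences, each tissue had its own blocks. Such blocks cannot take up plants shared by a root and a shoot library. The counts are lower than without a block in each root comparison and for the tissue difference in deficiency. They are higher in each shoot comparison and for the tissue difference in resupply.

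For the 6 comparisons within tissues there are 10 splits of 6 libraries, too few for a share under 0.05. The real split was the 1 with the most calls in each. The real count and the highest other were 767 and 3, 938 and 2, and 197 and 2 in roots. In shoots they were 1499 and 3, 2258 and 2, and 2504 and 3. Every other split mixes 2 conditions in each group, which turns a difference between them into spread. Few calls in those splits follow from this, so they give no level of false calls. The alternatives planned for gene lists were not run, because no list could be matched to the identifiers. Depth limits the genes near 0 in a tissue, more so if about 4 counts stand for 1 read pair, which is inferred only.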

Other observations

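The test of neighbouring identifiers was planned before its result was seen. Identifiers run in series, and genes that responded to deficiency alike had consecutive ones more often than chance. In roots, 23 pairs of consecutive identifiers changed in the same direction, against a median of 9 and a highest value of 18 in 1000 shuffles of the calls over tested genes (p = 0.001, permutation, the smallest these shuffles can give). In shoots there were 76 pairs, against a median of 39 and a highest value of 57 (p = 0.001, permutation, also the smallest possible). Zm00004b038609 and Zm00004b038610 are such a pair in deficient shoots, at 18.5 and 17.6 CPM against 4.48 and 3.7 in sufficient ones. That neighbours are duplicated genes with a shared response is a hypothesis; similar copies that exchange reads could give the same 23 and 76 pairs, and without a genome these were not separated.

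Zm00004b006197 and Zm00004b016768 rose in deficient roots and were higher still after resupply, at 24.1 and 77 CPM against 9.46 and 23.7. The further rise was not past the threshold (adjusted p = 0.054 and 0.15 for resupplied against deficient roots). In shoots Zm00004b018725 took another course than in roots: it rose from 39.3 to 66.5 CPM in deficiency and fell to 15.2 CPM on resupply, below sufficient shoots by a log2 fold change of -1.36 ± 0.13 (SE, n = 3, adjusted p = 0.00023).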
